A study of Mus musculus with 9 samples.

How the data were processed

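The data are 9 Affymetrix mouse whole-genome expression arrays (45101 probe sets), 1 per sample, with 3 samples of each Esrrg genotype. Per the labels, ventricles of male fetuses at the same embryonic day were kept in an RNA-preserving solution, total RNA was extracted on columns, and 6 µg of it was turned into biotinylated cRNA by the array maker's standard protocol. The deposited values are MAS5 signals, a linear intensity per probe set, as MAS5 is the tool named in the submitters' processing notes. Its version is not given in the sources used here. MAS5 combines the probe pairs of a probe set on 1 array at a time and scales each array by a factor. The mean of every deposited column without its top and bottom 2% came out at 200, so the arrays had been scaled to one trimmed mean and not otherwise normalized between each other. Array medians were 36.6, 37.5 and 45.9 in WT, 44.6, 40.7 and 39.7 in HET, and 37.8, 37.7 and 40.2 in KO. Detection calls were not used here. Such scaling leaves differences in array background and in the shape of the signal distribution, which weigh most on dim genes, and small signals are noisy because mismatch probes are subtracted.

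Probe sets were named by the platform annotation, with symbols updated by gene ID through a RefSeq gene table of GRCm38.p6. Of 45037 probe sets other than the 64 controls, 34945 name 1 gene, 932 several and 9160 none. Of those with 1 gene, 34741 symbols were found by gene ID and 204 were kept as the platform gives them. They cover 18193 genes. Signals were turned to log2(signal + 16), which understates changes of dim genes. For each gene the probe set with the highest mean over all 9 arrays was used, and 5165 genes whose mean lay under the 40th percentile of the probe sets (5.24 on the log2 scale, a signal of 21.7) were left out, which left 13028. Probe sets of a gene can disagree, as the 3 of Esrrg do.

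Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per genotype over all 9 arrays, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested within each comparison and a call at an adjusted p under 0.05. The comparisons were KO against WT, HET against WT, KO against HET, and HET against the mean of WT and KO. Exact permutation tests were used for Esrrg and the control probe sets. Gene lists (39 in number, 35 with at least 3 tested members, 679 of 746 entries matched to the array) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and limma's fry test as alternatives. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

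The rule named Esrrg, the 12 largest rises and 12 largest falls called between KO and WT whose KO and WT arrays do not overlap, 5 in each direction for the other genotype pairs and 3 for the midpoint. Where none passed, those with the smallest p in each direction were named as not called. Up to 4 members with the smallest p were named for each list described. Alternatives were quantile normalization, a shift of each array to one median, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, each probe set on its own, no intensity trend, array quality weights, only the 6 arrays compared, the replicate number as a block, and leaving out each array in turn.

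The array batch was read from the poly-A spike-in probe sets, at the widest gap between arrays in the log2 ratio of thr to dap. The ratio was chosen out of 9 control ratios looked at, after the leading principal component and genes called between KO and WT had parted the arrays in the same way. Of the 9, 4 part the arrays in that way and 5 do not. So the fit with the batch as a block, and the fit without the 2 arrays of lowest quality weight (HET replicate 1 and WT replicate 3), were chosen after seeing the data. The block leaves 5 residual degrees of freedom in place of 6.

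The fit was tested on simulated data with the real means and spreads of the 13028 genes, 200 of them changed between KO and WT, in 5 draws. It found 69.6% of the genes changed 2-fold and 40.4% of those changed 1.5-fold, with 31 false calls in all. With the batch as a block it found 31.2% and 6.4%, with 17 false calls. The simulated data held no batch difference and no correlated genes. So their false calls do not show how many genes called in the real data are false. Camera called an oxidative phosphorylation list lowered by -0.12 in 5 of 5 draws, with 0 calls in 145 tests of lists outside oxidative phosphorylation, in data without correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.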

Results

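Messenger RNA was measured in the cardiac ventricles of male mouse fetuses late in gestation, shortly before birth. The fetuses carried 2, 1 or no intact copies of Esrrg, the gene for estrogen-related receptor gamma (ERRγ), an orphan nuclear receptor that is known to bind many genes of mitochondrial energy metabolism. Each genotype, here called WT, HET and KO, was represented by 3 Affymetrix mouse expression arrays, described in the labels as biological replicates. The labels do not settle whether an array held RNA of 1 ventricle sample or of 3 pooled ones, so the p-values measure the spread between these arrays. The deposited signals had array medians from 36.6 to 45.9, and the number of arrays limits the precision. The Y-linked gene Eif2s3y had a signal of 247 to 382 on all 9 arrays, as male samples carry. The comparisons ask which ventricular genes differ when ERRγ is lost, and whether losing 1 copy has part of the effect.

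The targeted gene followed the labels on every array. The brightest Esrrg probe set gave 233 ± 41.5 in WT, 163 ± 1.02 in HET and 51.9 ± 10.9 in KO (signal, mean ± SD, n = 3 each). The KO mean was 22.2% of WT and the HET mean 69.8%. The WT arrays read 281, 213 and 206, the HET arrays 162, 164 and 162, and the KO arrays 58.3, 58.1 and 39.3, so the genotypes did not overlap. The fall from WT to KO was -1.88 ± 0.19 on the log2(signal + 16) scale (limma, adjusted p = 0.00018). An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1, the smallest such a design allows, for each pair of genotypes. The other 2 Esrrg probe sets were dim, with WT means of 42.2 and 38.4, and neither differed between KO and WT (limma, adjusted p = 0.939 and 0.928 over all probe sets). Where the probe sets lie relative to the altered part of the gene is not given in the sources used here.

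**Figure D1:**
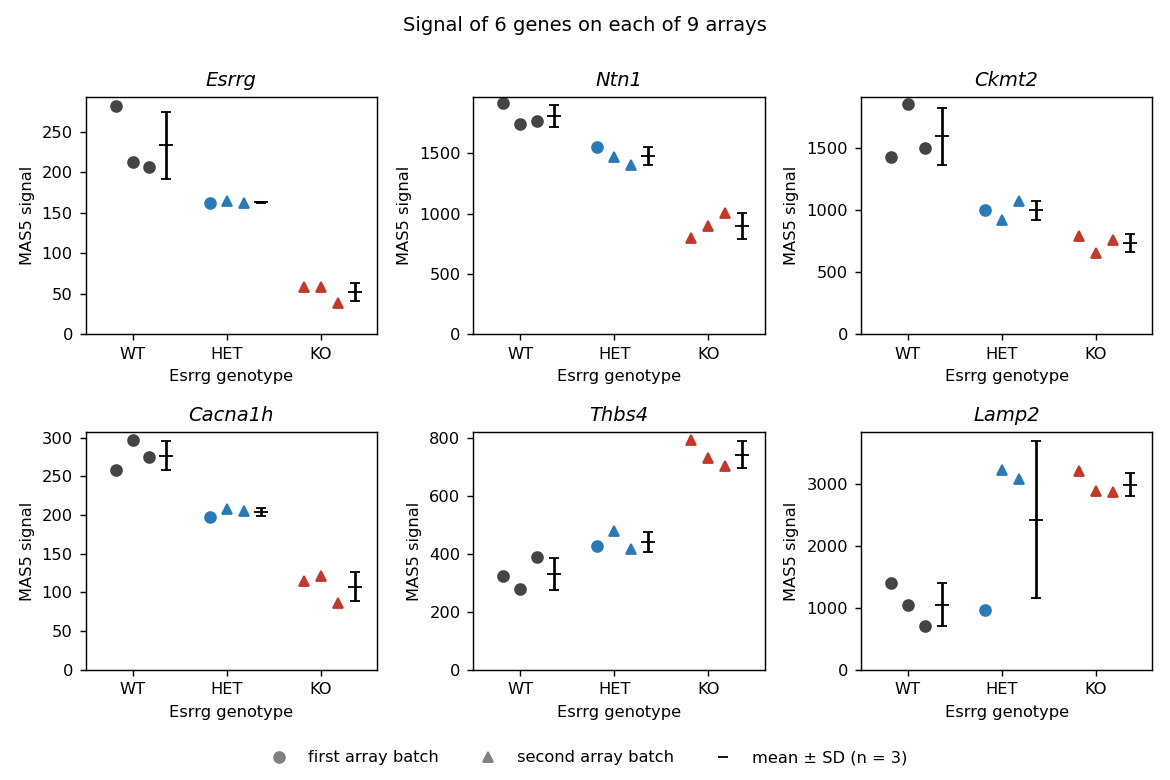
Deposited signal (linear axis from 0) of 6 genes on each array by Esrrg genotype, circles for the first and triangles for the second array batch, with the mean and SD of 3 arrays per genotype. Esrrg, Ntn1, Ckmt2 and Cacna1h stepped down from WT through HET to KO and Thbs4 stepped up, while the HET arrays of Lamp2 parted by batch, the HET difference between batches being 1.70 on the log2 scale.

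The arrays fell into 2 groups in control probe sets, here called array batches. No date or run is given in the sources used here, so a difference in handling is inferred from these probe sets alone. The partition was first seen in the leading principal component of the genes, which held 21.1% of the variance, and 9 ratios of control probe sets were then looked at. The batch was defined from one of them, the log2 ratio of the bacterial poly-A spike-ins thr and dap. In it the 3 WT arrays and HET replicate 1 read -1.03 to -0.82, and HET replicates 2 and 3 and the 3 KO arrays read -1.35 to -1.21. The ratio of thr to the mean of dap, lys and phe, the 3' minus 5' difference of dap (1.31 to 1.65 against 0.998 to 1.23) and that of Gapdh (-0.13 to -0.07 against -0.21 to -0.16) parted the arrays in the same way (exact two-sided permutation test over 126 ways of choosing 4 arrays, p = 0.00794 for each, the smallest these arrays allow). The other 5 ratios did not part them: dap to phe (exact permutation p = 0.762) and the 3' minus 5' differences of Actb (0.19), thr (0.238), phe (0.968) and cre (0.365). These p-values describe the separation and are not adjusted for the choice of ratios after the partition was seen. Of the ratios that parted the arrays in the same way, only that of Gapdh shares no probe sets with the thr to dap ratio. All WT arrays lay in the first batch and all KO arrays in the second, and only HET spanned both. A fit with the batch as a block takes KO minus WT as KO minus HET within the second batch plus HET replicate 1 minus WT within the first, and so rests on that single HET array. Its values are given below for the named genes and lists called, and for HET minus WT within the first batch.

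**Figure D2:**
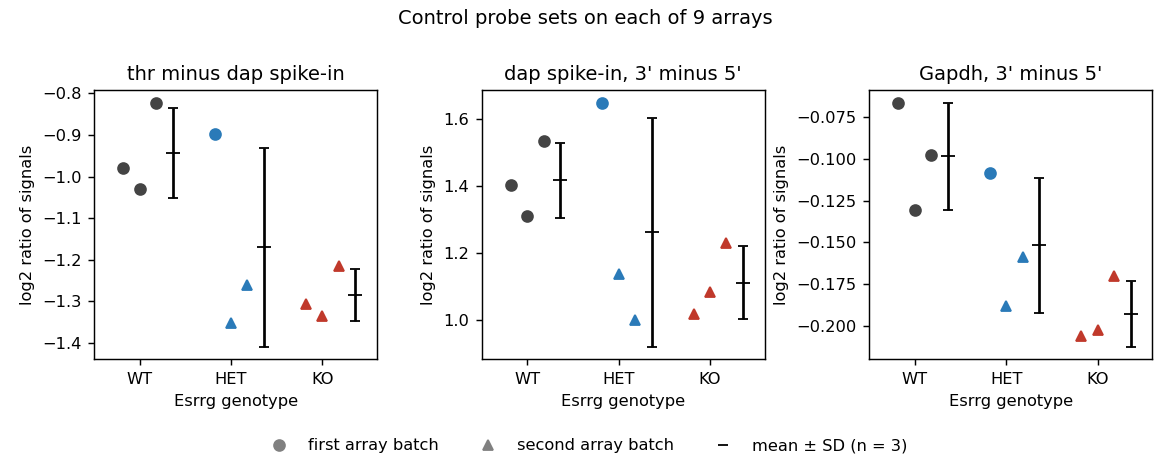
Log2 ratios of control probe sets on each array by genotype, for the spike-ins thr and dap, the 3' and 5' probe sets of dap, and those of Gapdh, with the mean and SD of 3 arrays. HET replicate 1 (circle) sat with the WT arrays in every panel, and the thr minus dap ratio differed by -0.36 between the batches.

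Between KO and WT ventricles, the deepest falls were in Gtsf1, a factor of the piRNA pathway (-1.90 ± 0.21), and Esrrg itself. Cacna1h, which encodes a T-type calcium channel, fell from 277 ± 19.2 to 107 ± 18.7 (log2 change -1.26 ± 0.15, adjusted p = 0.000903). Ckmt2, the mitochondrial creatine kinase of heart and skeletal muscle, fell from 1592 ± 227 to 738 ± 71.3 (-1.09 ± 0.11, adjusted p = 0.000184), and Ntn1, which encodes the secreted guidance protein netrin-1, from 1807 ± 90.8 to 897 ± 105 (limma, adjusted p = 0.00018). The synapsin gene Syn3 fell to a KO signal of 9.80 ± 7.3, under the level of 21.7 used to leave out dim genes, so the size (-1.59 ± 0.38) and rank of its fall are uncertain. Tmem71 (-1.54 ± 0.33), Anp32a (-1.19 ± 0.25), the peroxisomal oxidase gene Pipox (-1.17 ± 0.26), the neuropeptide gene Npb (-1.13 ± 0.26), the irisin precursor gene Fndc5 (-1.12 ± 0.21) and the metallothionein gene Mt3 (-1.01 ± 0.22) completed the 12 largest falls. Among rises, Lamp2, a lysosomal membrane protein gene, went from 1053 ± 353 to 2987 ± 187 (1.54 ± 0.33, adjusted p = 0.0339), the aminoacyl-tRNA synthetase gene Eprs from 284 ± 71.7 to 635 ± 17.2 (1.15 ± 0.15, adjusted p = 0.00139), and the thrombospondin gene Thbs4 from 332 ± 55.8 to 744 ± 46.9 (1.14 ± 0.13, adjusted p = 0.000395). The other large rises were Emp1 (1.37 ± 0.26), Zfp799 (1.21 ± 0.27), the myosin light chain gene Myl1 (1.10 ± 0.19), Svip (1.08 ± 0.25), Lrrc58 (1.07 ± 0.25), the beta-globin gene Hbb-b2 (1.05 ± 0.18, from a probe set that near-identical globin copies could share), Mreg (1.00 ± 0.24), 0610010F05Rik (0.97 ± 0.19) and Erbin (0.96 ± 0.21). Values after ± are limma standard errors for log2 changes and SDs over 3 arrays for signals.

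In all, limma called 211 of 13028 genes at an adjusted p under 0.05 between KO and WT, 96 higher and 115 lower in KO, and 2240 genes had an unadjusted p under 0.05. The KO and WT arrays did not overlap in any of the 211, and in 3251 of all genes tested (25.0%), where chance gives 10%. When each array was shifted to one median the split became 87 higher and 365 lower. With the array batch as a block, 1 gene was called, Kif22, which is not among the 211. Kif22 was very low on HET replicate 1. Without the block its KO minus WT log2 difference was 0.56 and was not called (limma, adjusted p = 0.666), while with the block it was a fall. The number of calls was 79, 12 and 10 without WT replicates 1, 2 and 3. Without KO replicates 1, 2 and 3 it was 17, 13 and 19. It was 840 without HET replicate 1, the one HET array in the batch of the WT arrays. Over the 211 genes the median size of the KO minus WT change was 0.589. The HET arrays of the second batch differed from the HET array of the first in the direction of the KO change in 181 of them, by a median of 0.259. The batch was defined after the called genes had been seen to part the HET arrays in this way. With the block, which uses the same KO and WT arrays the genes were picked by, 196 kept the direction of the KO change, with a median of 0.25, and 69 had an unadjusted p under 0.05.

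Named genes differed in how far they moved with the batch. With the batch as a block, the KO minus WT log2 difference was -1.89 ± 0.34 for Esrrg, -1.50 ± 0.37 for Gtsf1, -1.32 ± 0.28 for Cacna1h, -1.08 ± 0.19 for Ckmt2, -0.89 ± 0.16 for Ntn1, 1.08 ± 0.22 for Thbs4 and 0.95 ± 0.25 for Eprs, though none of these passed the adjusted threshold in that smaller fit (limma, adjusted p = 0.168 for Esrrg, Ckmt2 and Ntn1, 0.502 for Eprs). By contrast it was -0.16 ± 0.29 for Lamp2, -0.03 ± 0.24 for Erbin, 0.04 ± 0.33 for Lrrc58, 0.08 ± 0.24 for Emp1 and 0.21 ± 0.39 for Zfp799. Other rises were smaller with the block, at 0.36 ± 0.40 for Svip, 0.49 ± 0.28 for Hbb-b2, 0.59 ± 0.30 for Myl1, 0.67 ± 0.42 for Mreg and 0.77 ± 0.34 for 0610010F05Rik. The other falls gave -2.15 ± 0.57 for Tmem71, -1.49 ± 0.45 for Anp32a, -1.15 ± 0.47 for Npb, -1.06 ± 0.48 for Pipox, -0.94 ± 0.67 for Syn3, -0.83 ± 0.37 for Fndc5 and -0.81 ± 0.39 for Mt3. Among the HET arrays, Lamp2 differed by 1.70 and Emp1 by 1.29 between the second and the first batch, against 0.01 for Esrrg and -0.01 for Ckmt2.

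**Figure D3:**
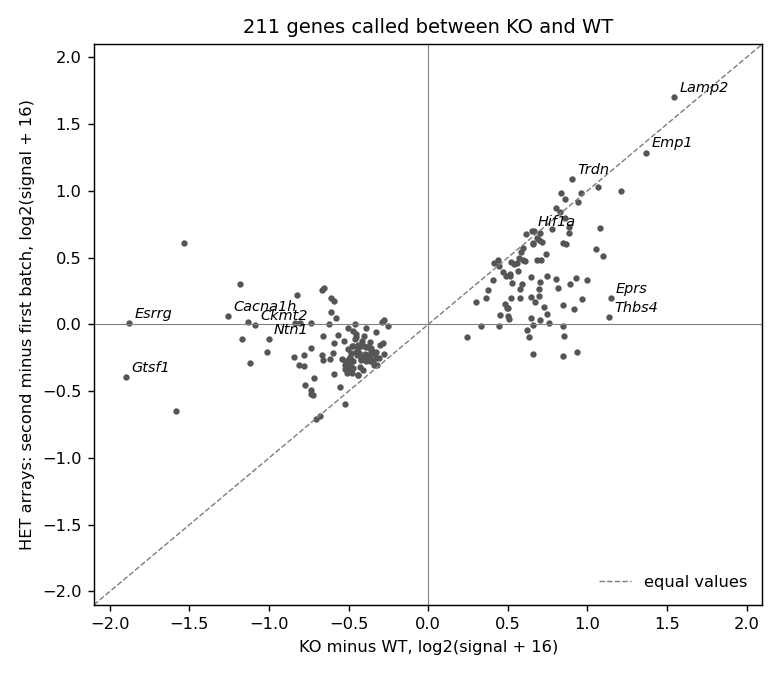
Each point is 1 of the 211 genes called between KO and WT, with the KO minus WT difference on the x axis and the difference between the HET arrays of the second and first batch on the y axis, both in log2(signal + 16). Lamp2 and Emp1 lay near the dashed line of equal values, at 1.70 and 1.29 on the y axis, and Esrrg, Ckmt2, Cacna1h and Thbs4 lay near 0, at 0.01, -0.01, 0.06 and 0.06.

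Genes of mitochondrial energy metabolism were lower as groups in KO than in WT, by small amounts. Of 74 tested genes of oxidative phosphorylation, 67 were lower in KO, the median log2 difference was -0.12, and 3 fell on their own test: the complex I genes Ndufs1 (-0.30 ± 0.06, adjusted p = 0.0339) and Ndufb3 (-0.34 ± 0.08) and the complex IV gene Cox5b (-0.33 ± 0.08). Adjusted over the list alone, 24 fell and 2 rose. Of 24 genes of fatty acid oxidation, 19 were lower, with a median of -0.18. Eci1 (-0.41 ± 0.07, adjusted p = 0.0225), Hadha (-0.36 ± 0.07), Acaa2 (-0.33 ± 0.07), Fabp3 (-0.28 ± 0.06) and Hadh (-0.28 ± 0.06) fell, and 13 fell and 1 rose when adjusted over the list alone. Of 68 mitochondrial ribosomal protein genes, 59 were lower, with a median of -0.20. Mrpl48 (-0.47 ± 0.11, adjusted p = 0.0445), Mrps35 (-0.39 ± 0.09) and Mrpl35 (-0.39 ± 0.09) fell, and 15 when adjusted over the list alone. With limma's camera test the list adjusted p was 1.7e-06 for oxidative phosphorylation, 0.000243 for fatty acid oxidation and 6.9e-08 for the mitochondrial ribosome. Each call was lost with an estimated correlation between genes (adjusted p = 0.591 for all of them).

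These groups moved with the array batch. With the batch as a block, the median KO minus WT difference was 0.01 for oxidative phosphorylation (camera adjusted p = 0.90), -0.07 for fatty acid oxidation (0.524) and -0.03 for the mitochondrial ribosome (0.498). The genes called in these lists shrank with the block, to -0.15 for Ndufs1, -0.03 for Ndufb3, -0.08 for Cox5b, -0.25 for Eci1, -0.18 for Hadha, -0.12 for Acaa2, -0.15 for Fabp3, -0.06 for Hadh, -0.20 for Mrpl48, -0.17 for Mrps35 and -0.11 for Mrpl35. Between the HET arrays of the second and first batch the median differences were -0.14, -0.14 and -0.15. Within the second batch, KO minus HET had medians of 0.02, -0.05 and -0.0019, with camera adjusted p of 0.556, 0.21 and 0.945. Under quantile normalization the call for oxidative phosphorylation was lost as well (median -0.05, camera adjusted p = 0.534). Of its parts, complex I (median -0.15, adjusted p = 0.000198), complex III (-0.13, 0.0381) and complex V (-0.12, 0.00845) passed the camera test, and complex II (-0.15, 0.11) and complex IV (-0.09, 0.223) did not. With an estimated correlation the adjusted p was 0.591 for complexes I, III and V, and with the batch as a block it was 0.846, 0.90 and 0.731 (medians 0.02, 0.0015 and -0.02). The complex III call was also lost without WT replicate 2 (0.0857) or 3 (0.167), HET replicate 3 (0.0521), or KO replicate 1 (0.121), 2 (0.0553) or 3 (0.0598), and that of complex V without WT replicate 3 (0.0783) or KO replicate 1 (0.0777).

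**Figure D4:**
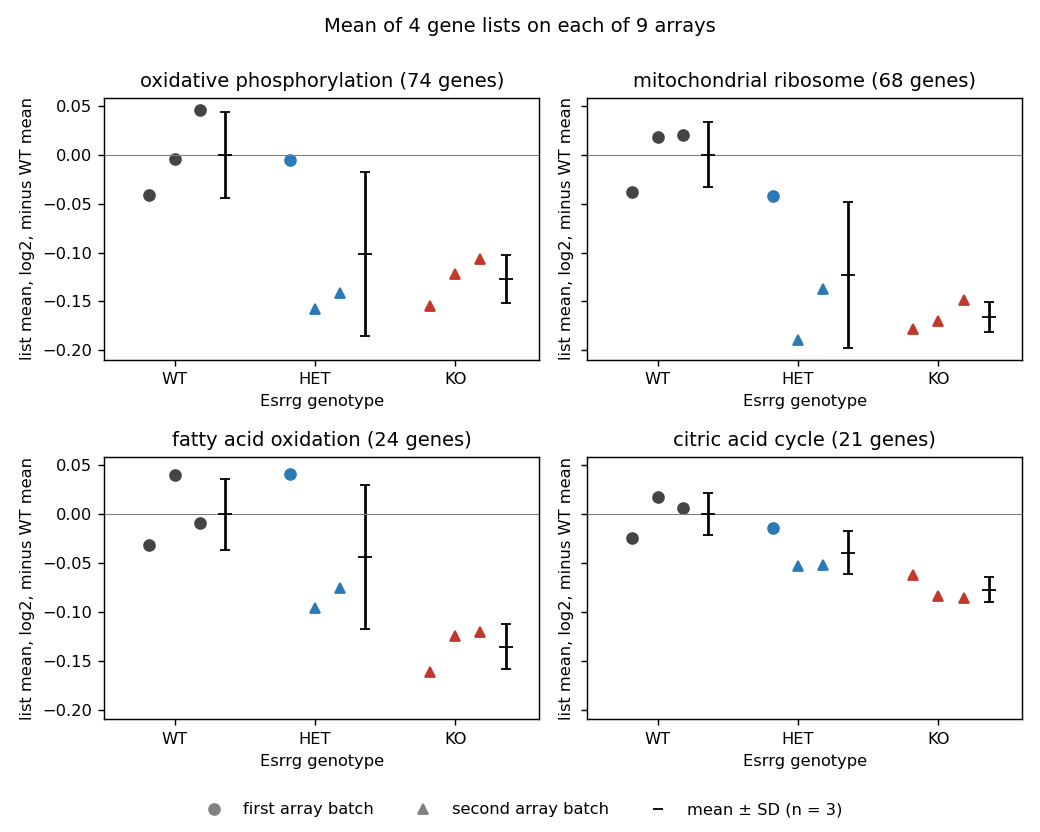
Mean over the tested genes of 4 lists on each array, in log2(signal + 16) minus the mean of the WT arrays, by genotype, with the mean and SD of 3 arrays. In the oxidative phosphorylation and mitochondrial ribosome panels HET replicate 1 (circle) sat near the WT arrays and HET replicates 2 and 3 (triangles) near the KO arrays. In the oxidative phosphorylation panel they read -0.01, -0.16 and -0.14.

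Genes that supply and carry that energy did not all move one way. Of 21 genes of the citric acid cycle and pyruvate dehydrogenase, 15 were lower and Pdhb, a pyruvate dehydrogenase subunit, fell (-0.25 ± 0.06, adjusted p = 0.0386; -0.24 ± 0.08 with the batch block). Mdh1 (-0.27), Pdhx (-0.29) and Idh3g (-0.26) did not pass (-0.04, -0.22 and -0.06 with the block), though 4 genes fell when adjusted over the list alone. The list did not pass either (median -0.11, camera adjusted p = 0.13, and 0.591 with an estimated correlation). Its median was -0.04 with the batch block. It passed when each array was shifted to one median (camera adjusted p = 0.0338). Of 22 genes of glycolysis and glucose uptake 17 were lower and none passed, the lowest p being those of Eno3 (-0.26), Pfkl (-0.27), Ldhb (-0.17) and Pkm (-0.20), which gave -0.05, -0.23, -0.02 and 0.06 with the block. The list had a median of -0.12 and passed (camera adjusted p = 0.0143), but not with an estimated correlation (adjusted p = 0.591), with the batch block (median -0.02, adjusted p = 0.498), or without WT replicate 2 (0.0652) or 3 (0.058). Among 14 genes of energy transfer, Ckmt2 and the nucleotide carrier gene Slc25a5 (-0.31 ± 0.07) fell and Vdac3, a porin of the outer mitochondrial membrane, rose (0.30 ± 0.07), with a list adjusted p of 0.263. With the batch block Slc25a5 and Vdac3 gave -0.05 ± 0.09 and 0.13 ± 0.11. Among 29 genes of mitochondrial import and biogenesis, the elongation factor gene Tufm (-0.74 ± 0.14) and Tomm7 (-0.48 ± 0.10) fell and Tomm20 rose (0.61 ± 0.14), with a list adjusted p of 0.208. With the batch block Tufm, Tomm7 and Tomm20 gave -0.22, -0.12 and -0.07. Adjusted over each list alone, 6 fell and 3 rose for import and biogenesis. For energy transfer 3 fell and 1 rose, and for glycolysis 2 fell.

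Of 23 ion channel genes tested, 2 fell. Adjusted over the list alone, 3 fell and 3 rose. Besides Cacna1h, Kcne1, a regulatory subunit of the slow delayed rectifier potassium channel, went from 2245 ± 168 to 1510 ± 241 (log2 change -0.58 ± 0.10, adjusted p = 0.0255; -0.63 ± 0.18 with the batch block). Kcnj12 (0.72 ± 0.22, adjusted p = 0.101; 0.70 ± 0.40 with the block) and Gja1 (0.34 ± 0.11, adjusted p = 0.115; -0.15 ± 0.12 with the block) did not pass, nor did the list (median -0.04, camera adjusted p = 0.646). Of 15 calcium handling genes, the calsequestrin gene Casq2 fell (-0.44 ± 0.09) and the triadin gene Trdn rose (0.91 ± 0.20), but with the batch block they gave -0.06 ± 0.11 and -0.18 ± 0.15, and the list did not pass (0.223). None of 24 sarcomere genes was called over all genes tested (list camera adjusted p = 0.191). When adjusted over the list alone, 5 fell and 1 rose.

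Among 12 genes of the fetal and stress program, Nppa, which encodes atrial natriuretic peptide, rose from 13050 ± 133 to 15440 ± 651. Its log2 change was 0.24 ± 0.06 (limma, adjusted p = 0.0459), and 0.34 ± 0.08 with the batch block. The list did not pass (camera adjusted p = 0.612), though 3 members rose and 4 fell when adjusted over the list alone. Among 22 genes of ERR partners and coactivators, Perm1, a muscle gene induced by PGC-1 and ERR, fell (-0.72 ± 0.14, adjusted p = 0.0291; -0.31 ± 0.22 with the block) and Hif1a rose (0.65 ± 0.14, adjusted p = 0.0383; -0.05 ± 0.14 with the block), with a list adjusted p of 0.726. Gpx3, a secreted glutathione peroxidase, fell from 4791 ± 136 to 3231 ± 109 among 17 antioxidant genes. Its log2 change was -0.57 ± 0.07 (limma, adjusted p = 0.00078), and -0.49 ± 0.11 with the block. The antioxidant list passed with the fry test (adjusted p = 0.0445), but not with camera (0.208, and 0.591 with an estimated correlation). When adjusted over the list alone, 2 members rose and 2 fell. Cell cycle genes were lower in 22 of 29 cases with a median of -0.18 (camera adjusted p = 0.00319), and Cdc20 fell (-0.42 ± 0.09, adjusted p = 0.0371; -0.16 ± 0.14 with the block). Adjusted over the list alone, 10 fell and 1 rose. The list call was lost with an estimated correlation (adjusted p = 0.591) and with the batch block (median -0.14, adjusted p = 0.461). The lists for the integrated stress response (0.223), hypoxia (0.726), immediate early genes (0.469) and heat shock (0.841) did not pass. No member was called over all genes tested. When adjusted over each list alone, 2 heat shock genes rose and 2 fell, and no member of the others passed.

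No list of cell type markers passed between KO and WT with all arrays and the signals as scaled. The adjusted camera p was 0.538 for atrium, 0.768 for ventricle, 0.0894 for fibroblasts, 0.837 for endothelium, 0.139 for smooth muscle and pericytes, 0.612 for epicardium, 0.488 for erythroid cells, 0.508 for macrophages and leukocytes, 0.854 for liver, 0.612 for neural cells, 0.325 for skeletal muscle and 0.841 for sex-linked genes. The fibroblast list passed under quantile normalization (0.0216) and without WT replicate 1 (0.0115), but not with an estimated correlation (adjusted p = 0.591, and 0.931 with the batch block). Its median was 0.06, and 0.24 with the batch block (adjusted p = 0.0602), and 4 of its 13 genes rose when adjusted over the list alone. Single markers did change. The fibroblast gene Lum rose (0.33 ± 0.08, adjusted p = 0.0482), the epicardial gene Tbx18 rose (0.84 ± 0.17, adjusted p = 0.032), and the endothelial receptor gene Kdr fell (-0.74 ± 0.14, adjusted p = 0.0262). With the batch block they gave 0.34 ± 0.13, 0.23 ± 0.25 and -0.25 ± 0.19. Few markers were tested for erythroid cells (5 of 14), liver (3 of 11), neural cells (4 of 11) and skeletal muscle (6 of 13), so those lists say little. The lists for thymus, lung and brown fat had under 3 tested members, and that for genes of the mitochondrial DNA had none.

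Losing 1 copy of Esrrg gave no gene past the threshold. The changes with the smallest p were lower Gtpbp2 (-1.04 ± 0.17, adjusted p = 0.0973), Tufm (-0.83 ± 0.14, 0.0973), Ckmt2 (-0.66 ± 0.11, 0.0973), 0610012G03Rik (-0.43 ± 0.08, 0.23) and Cntd1 (-0.73 ± 0.15, 0.285), and higher Tspan12 (0.99 ± 0.17, 0.119), the glucose transporter gene Slc2a3 (0.66 ± 0.13, 0.23), Nup153 (0.81 ± 0.16, 0.23), Cog8 (0.77 ± 0.16, 0.23) and 3000002C10Rik (0.56 ± 0.11, 0.23), in limma log2 differences of HET minus WT with adjusted p. Within the first batch, in the same order, they gave -1.33, -0.48, -0.65, -0.26 and -0.73, and 0.77, 0.72, 0.46, 0.93 and 0.28. Esrrg differed by -0.47 ± 0.19 (adjusted p = 0.376), and by -0.47 within the first batch. Limma called 0 of 13028 genes, with 1499 at an unadjusted p under 0.05. It called 574 without HET replicate 1, the one HET array that shared a batch with WT, and 1 without HET replicate 3. With the batch as a block it called 2, Kif22 and Adck2, both low on HET replicate 1 alone (-2.32 ± 0.24 and -1.89 ± 0.28 against WT) and named after their values were seen.

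The mitochondrial lists were lower in HET than in WT too. The median was -0.10 for oxidative phosphorylation (66 of 74 lower, camera adjusted p = 1.1e-05), -0.12 for the mitochondrial ribosome (56 of 68 lower, 4.9e-06), -0.12 for complex I (0.00139) and -0.10 for complex V (0.0121). Sarcomere (-0.09, 0.0227) and cell cycle genes (-0.13, 0.00105) were also lower, and epicardial markers were higher in all 9 cases (0.25, 0.0179). Every one of these 7 calls was lost with an estimated correlation (adjusted p = 0.629) and with the batch as a block. With the block the median was -0.0046 for oxidative phosphorylation (0.843), 0.02 for complex I (0.981), -0.04 for complex V (0.736), -0.05 for the mitochondrial ribosome (0.324) and -0.03 for sarcomere genes (0.807). For cell cycle genes (-0.15, 0.219) and epicardial markers (0.35, 0.324) the median did not shrink with the block, where HET minus WT rests on 1 HET array. Fatty acid oxidation (-0.10, 0.076), the citric acid cycle (-0.05, 0.407), glycolysis (-0.07, 0.407) and ion channels (-0.01, 0.989) did not pass.

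Between KO and HET, which asks what the remaining copy does, 2 genes were called and both fell. Esrrg differed by -1.41 ± 0.19 and Ntn1 by -0.71 ± 0.09 (limma, adjusted p = 0.00862 for both). They were also the 2 called with the batch as a block, a comparison made within the second batch (-1.41 and -0.67, adjusted p = 0.0434 for both). Of 13028 genes, 626 had an unadjusted p under 0.05. No gene was called without HET replicate 2, HET replicate 3, KO replicate 1 or KO replicate 2. Fatty acid oxidation was lower in KO than in HET (median -0.11, 20 of 24 lower, camera adjusted p = 0.0115), but not with an estimated correlation (adjusted p = 0.925) or within the second batch (median -0.05, adjusted p = 0.21). Oxidative phosphorylation (-0.03, 0.493), the citric acid cycle (-0.03, 0.496), glycolysis (-0.06, 0.10), the mitochondrial ribosome (-0.05, 0.26) and ion channels (0.01, 0.514) did not pass. Of the ion channel genes, 2 fell and 0 rose when adjusted over the list alone. Within the second batch, fibroblast markers were higher in KO than in HET (median 0.12, camera adjusted p = 0.0337), but not with an estimated correlation (adjusted p = 0.929). With the arrays of both batches the median was 0.08 (camera adjusted p = 0.10, and 0.925 with an estimated correlation).

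No gene departed from the midpoint of WT and KO in HET ventricles past the threshold. Tcl1b3 (0.50), Rtkn (0.48) and Itga3 (0.58) lay highest above the midpoint by p and Gtpbp2 (-0.76), Cntd1 (-0.62) and Mettl18 (-0.69) lowest, each with a limma adjusted p of 0.983. Esrrg lay 0.47 above it, with the same adjusted p. Limma called 0 of 13028 genes, with 570 at an unadjusted p under 0.05, and 1 without HET replicate 3. Over the 211 genes called between KO and WT, the median departure turned to the KO direction was 0.04, against a median KO minus WT change of 0.589. All WT arrays lay in the first batch, all KO arrays in the second, and HET in both. A batch difference alone would thus also place HET between WT and KO. So a median near the midpoint does not show an effect of 1 lost copy. Of the lists, epicardial markers lay above the midpoint (median 0.31, camera adjusted p = 0.0203), but not with an estimated correlation (adjusted p = 0.863) or with the batch as a block (0.14), where the median stayed at 0.31.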

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

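The array batch, the control ratio that defines it, the tests of the batch and the test of the label on HET replicate 1 were chosen after the results were seen. The counts over other splits of the arrays were planned.

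Outside the gene tests, some control ratios differed between KO and WT, which cannot be told apart from the batch. The thr minus dap ratio of the spike-ins, which defines the batch, differed by -0.341 (log2, KO minus WT). The 3' minus 5' difference of dap, which parted the arrays in the same way, differed by -0.305. Among the ratios that did not part the arrays, KO minus WT ran from -0.027 for cre to 0.158 for thr (both 3' minus 5'). Of 3482 probe sets at or above the filter level that name no gene or several, limma called 11 between KO and WT. Of these, 9 were higher and 2 lower in KO. An unadjusted p under 0.05 was reached by 447, and none was called with the batch as a block.

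The 211 genes called between KO and WT were weighed against the array batch. The HET arrays of the second batch differed from the HET array of the first in the KO direction by a median of 0.259, against a KO minus WT median of 0.589. The HET arrays took no part in the direction of the KO change. But the called genes had parted the HET arrays in this way before the batch was defined, so this is no separate test of the batch. A batch difference may account for part of the KO change, though a single array stands for the first batch and the labels name no batch. A wrong label on HET replicate 1 is argued against by its Esrrg signal of 162.1. That lies below the lowest WT array at 206.4 and close to the other HET arrays. It rests on the brightest Esrrg probe set, where HET and WT did not differ past the threshold (limma, adjusted p = 0.376). On the dim probe sets, which did not part KO from WT either, HET replicate 1 lay within the WT range (52.8 and 34.9). Within the second batch KO minus HET had a turned median of 0.132. Genes picked by their KO and WT values in simulated data without a genotype effect gave 0.206. Those data held no batch difference either (turned HET median -0.00298, against 0.259 here). So 0.206 does not measure what picking brings when a batch moves the genes, and 0.132 cannot be judged against it. For the 211 genes as a set the genotype and the batch cannot be told apart.

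The lower oxidative phosphorylation and fatty acid oxidation lists could come from the batch. The mean of the oxidative phosphorylation list differed by -0.127 between KO and WT and by -0.144 between the HET arrays of the second and first batch. For fatty acid oxidation these were -0.135 and -0.127. With the batch as a block the KO minus WT mean of oxidative phosphorylation was 0.0168, with a 95% interval of -0.106 to 0.139. That interval leaves out the -0.127 seen without the block, though it rests on HET replicate 1. Without the block the 95% interval was -0.24 to -0.0147, and the intervals overlap. A smaller fall in the KO genotype, the explanation the design offers, lies within the blocked interval and stays open.

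The fall of Esrrg and Ntn1 between KO and HET is not accounted for by the batch, because both passed among the arrays of the second batch (adjusted p = 0.0434 for the higher of the 2). Ckmt2, Cacna1h, Thbs4 and Eprs showed HET arrays between WT and KO, with differences of 0.20 or less between the HET arrays of the batches. None of the 4 passed between HET and WT (adjusted p = 0.0973, 0.358, 0.31 and 0.293 in that order) or between KO and HET (0.947, 0.117, 0.102 and 0.989).

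Other splits were counted for each result. Groups of 3 against 3 make 10 splits, too few for a share under 0.05. The 211 genes of KO against WT were reached by 1 of 10 splits, the real one, and the highest other gave 0. The real split is also the split by batch, and every other one mixes batches and genotypes in both groups. Low counts in the others were thus likely beforehand, and they do not part genotype from batch. The 8 lists were reached by 1, and the highest other gave 6. For HET against WT the real count was 0 genes, which all 10 reach whatever the data, the highest other giving 27, and the 7 lists by 1, the highest other giving 6. The split with 27 set HET replicates 2 and 3 with WT replicate 1. For KO against HET, 2 splits gave the real 2 genes or more, the highest other also 2, and 5 gave the real 1 list or more, the highest other 5. For the midpoint, the real count of 0 genes is reached by 100 of 100 seeded regroupings whatever the data, so that count says nothing on chance. The real 1 list was reached by 64 of them, so chance cannot be excluded for it. The highest others gave 155 genes and 9 lists. The 155 genes came with WT replicates 1 and 3 and HET replicate 1 as the middle group, and 147 with the 3 WT arrays, which points to a structure of the samples. Middle groups that spanned both batches gave 2 genes or fewer. Those within one batch varied: HET replicate 2 with KO replicates 1 and 2 gave 100 and 0, the 3 KO arrays 6, 36 and 8, WT replicates 1 and 2 with HET replicate 1 gave 3 and 2, and the rest 4 or fewer.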

How the results depend on the processing

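The batch block and the fit without the 2 arrays of lowest weight were added after the data were seen. The cause of a change was not tested unless named. The 211 genes called between KO and WT became 452 with arrays shifted to one median, 85 without a filter (more genes tested), 7 with the mean of a gene's probe sets, 6 without an intensity trend, 612 with array weights, 773 with only the 6 arrays compared, 441 without the 2 arrays, 1 with the batch block, and 10 to 840 without single arrays. All 211 were among the 612 and the 773, and 198 among the 452. The weights came from a fit without the batch, where HET replicate 1 had the lowest (0.455). A batch difference among the HET arrays can lower that weight too, so it need not mean poor quality. The 612, 773, 441 and 840 all came with HET replicate 1, the one HET array in the WT batch, weighted down or left out. These counts are therefore no check of the calls against the batch. For HET against WT the 0 became 3, 9, 230 and 2 with the median shift, weights, the 2 arrays left out and the batch block, and 0 to 574 without single arrays. For KO against HET the 2 became 0 with the mean of probe sets, without a trend, with only 6 arrays and without the 2 arrays, and 0 to 3 without single arrays. Genes off the midpoint were 2 without the 2 arrays and 0 to 1 without single arrays.

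The replicate numbers did not pair the arrays. Residuals of same-numbered arrays correlated at -0.04 to 0.05, those of other numbers at -0.06 to 0.08, and 3 of 9 arrays matched best with their own number. With the replicate number as a block, 127 genes were called between KO and WT (121 of the 211) and 1 between HET and WT.

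Esrrg was lower in KO than in WT in every setting, and from -1.95 to -1.74 without single arrays. With the mean of its probe sets, 2 of which are dim (-0.72, adjusted p = 0.125) and with the batch block (-1.89, adjusted p = 0.168) it missed the threshold.

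The 8 lists called became 4 with quantile normalization, the mean of probe sets, each probe set on its own or fry, 0 with an estimated correlation or the batch block, and 5 to 9 without single arrays. The oxidative phosphorylation median was -0.0504 with quantile normalization and 0.0095 with the batch block, and -0.118 with an estimated correlation and fry, none called. Complex I turned to 0.0249 with the batch block. Fatty acid oxidation gave -0.0728 with the batch block and -0.183 with an estimated correlation, and the mitochondrial ribosome -0.0272 and -0.201, none called. Glycolysis missed with quantile normalization (-0.054), the mean of probe sets (-0.0926), each probe set (-0.108), the batch block (-0.0186), and an estimated correlation and fry (-0.122), and ranged from -0.165 to -0.114 without single arrays. The citric acid cycle passed with arrays shifted to one median (adjusted p = 0.0338) and with fry (0.0445). Of the 4 lists passing fry, fatty acid oxidation and the mitochondrial ribosome were among the 8, and the citric acid cycle and antioxidant genes (0.0445) were not. Of the 4 with quantile normalization the fibroblast list (0.0216) was not.

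Among the named genes called between KO and WT, the sign turned with the batch block for Lamp2 (-0.16), Erbin (-0.0275), Hif1a (-0.0468), Tomm20 (-0.0661) and Trdn (-0.18), and with the mean of probe sets for Slc25a5 (0.10). Of the 24 genes named between KO and WT, 24 stayed called with the median shift, weights and only 6 arrays, 19 with quantile normalization, 11 without a filter, 5 without a trend, 4 with the mean of probe sets and 0 with the batch block. Without WT replicate 1, 2 or 3 it was 12, 7 and 7, without KO replicate 1, 2 or 3 10, 8 and 8, and without HET replicate 1, 2 or 3 24, 22 and 23. Genes near the filter level of 21.7 are limited by signal over background.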

Other observations

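Genes close to Esrrg were tested for a passenger effect, a test chosen after the results were seen. In a targeted strain the genome next to the altered allele can come from another mouse strain, and variants there could change signals of neighbouring genes or of their probes. Of the 140 tested genes nearest to Esrrg in gene order (up to 100 on each side, GRCm38.p6), 4 were called between KO and WT, or 2.86%, against 1.6% of the 12866 others (Fisher's exact test, two-sided, p = 0.292). They were Eprs (1.15), Sertad4 (0.66), Zbtb18 (0.87) and Smyd2 (-0.33), log2 KO minus WT, named after their values were seen. The number of genes is too small to tell. With the array batch as a block Eprs, Sertad4, Zbtb18 and Smyd2 gave 0.95, 0.66, 0.27 and -0.13, and 6, 26, 56 and 3 tested genes lay between them and Esrrg.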
